A study of Arabidopsis thaliana with 6 samples.

How the data were processed

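Gene expression was measured in leaf 3 of Arabidopsis thaliana (Col-0), dissected from seedlings at an age the labels give as 9 DAS, on AGRONOMICS1 whole-genome tiling arrays hybridised with biotin-labelled total RNA. Per the labels' protocols, all seedlings were moved to medium with 5 µM dexamethasone for 4 h before harvest. There were 3 arrays of a strong ERF6-overexpressing line (ERF6:IOE) and 3 of the control line (GFP:IOE), called biological repeats 1 to 3 in the labels, and the series' design text states that the samples came from independent experiments.

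The authors deposited 1 table of log2 expression values with 30237 rows and 6 arrays. Per the submitters' processing notes, RMA and limma were used and TAIR9 was the genome build. Their versions and settings are not given in the sources used here. RMA subtracts background, quantile-normalises the arrays and summarises the probes of a gene, so overall shifts between arrays are removed by construction and values near the floor are compressed. The deposited log2 values ranged from 2.16 to 14.2, and array medians from 4.85 to 4.90. The table holds no detection calls, so whether a transcript was detected was not assessed. Sequencing depth has no counterpart here, and the number of arrays limits the precision.

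Rows are named by locus code with a suffix whose meaning is not given in the sources used here. The 30237 rows cover 29920 loci, of which 208 have more than 1 row, and each row was tested on its own. Symbols were taken by locus from a name table of assembly TAIR10.1, in which 29715 rows matched and 522 did not, and 10513 rows received a symbol other than the locus code. Because the builds differ, no coordinates are given. Probes shared between close paralogs cannot be told apart in these values.

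Lines were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, ERF6:IOE minus GFP:IOE, with no filter on level and Benjamini-Hochberg adjustment over all rows. The threshold was an adjusted p of 0.05, and the tests of single genes and of gene lists were two-sided. Adjusted p-values of single genes are from this fit. SE is the moderated standard error of the log2 fold, with a median of 0.13 over all rows. Arrays within a line correlated across rows with r from 0.984 to 0.987 and arrays of different lines with r from 0.977 to 0.983. No pair of arrays held identical values, and each array was counted as 1 replicate.

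The main test, the gene lists, the rule for named genes and all alternatives other than those said to be chosen later were fixed before the data were examined. The 27 gene lists hold 370 members, of which 361 were measured. There was no row for 8 members, and TIP41 was left out because the name table gives that symbol to another locus. A member with several rows was represented by its brighter row. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists, and again with the correlation estimated from the arrays and with fry. Camera compares a list with all other genes, whereas fry tests whether its members move on balance in one direction.

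Genes were named by rule. ERF6 was always named, as were GA2OX6, ERF11, WRKY33, MYB51, STZ and ERF5. Among called genes on the same side in all 3 repeats, the 16 with the largest upward and the 12 with the largest downward log2 fold were taken, and only 8 passed downward. Up to 4 members of each list with the largest absolute moderated t were added. WRKY15, WRKY30, PR4, RBOHD, PR5, PEN2, PR1 and the genes in the opening of the other observations were named after their values were seen.

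The procedure was tested on simulated data for the same comparison and 30237 rows, with 200 rows changed in each of 10 runs. It recovered 20% of changes of 1.5-fold, 83.9% of 2-fold and 98.9% of 4-fold, and 4.86% of the calls were false. Of lists shifted by 0.5 or -0.25, 20 of 20 were called, against 2 of 250 lists that were not shifted. The simulated rows were drawn independently, with no correlation between genes and no effect of the repeat number. These shares therefore do not measure how often a gene or a list is falsely called, or a change is missed, in the real arrays. Alternatives were a fit with the repeat number as a block, filters on dim rows, renewed quantile, median and cyclic loess normalization, a variance trend with a robust prior, array weights, a minimum fold of 1.5, the other list tests, and leaving out each repeat and each array.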

Results

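The data were 6 arrays of leaf 3 from seedlings on dexamethasone for 4 h, 3 of the ERF6-overexpressing line ERF6:IOE and 3 of the control line GFP:IOE. ERF6 (ETHYLENE RESPONSE FACTOR 6, AT4G17490) is a transcription factor of the AP2/ERF family. Both lines received dexamethasone, so the comparison addressed which transcripts differ between the lines after 4 h of it in growing leaves. Without arrays from before induction, differences between the lines that predate it are included. Rose and fell mean higher and lower in ERF6:IOE than in GFP:IOE. Values are log2 expression as mean ± SD with n = 3 arrays per line.

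ERF6 transcript was higher in ERF6:IOE in all 3 repeats, at 10.1 ± 0.25 against 7.27 ± 0.34 in GFP:IOE. The log2 fold was 2.85 (SE 0.20), or 7.22-fold, with an adjusted p of 0.00107 (limma). Transcript of the introduced gene and of the resident gene were not distinguished. ERF5, a close relative of ERF6, did not pass the test (log2 fold -0.15, 95% interval -0.44 to 0.13).

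Most genes that passed the test rose in ERF6:IOE. Of 30237 rows, 219 (0.724%) passed, 211 higher and 8 lower. The rise was at least 2-fold for 130 genes, at least 4-fold for 41 and at least 16-fold for 9, and the fall was at least 2-fold for 3. All 219 differed in the same direction in 3 of 3 repeats, with no overlap between the lines. Lack of overlap implies the shared direction, and a call with 3 arrays per line nearly requires it, so neither adds support. Over all rows, 13.5% did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1451 rows higher and 975 lower, against 1512 rows in total that chance would give. The number of calls depended on the number of arrays, and with 1 array left out from 87 to 126 rows were higher and from 1 to 6 lower. In a fit with the repeat number as a block, 143 rows were higher and 5 lower.

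**Figure D1:**
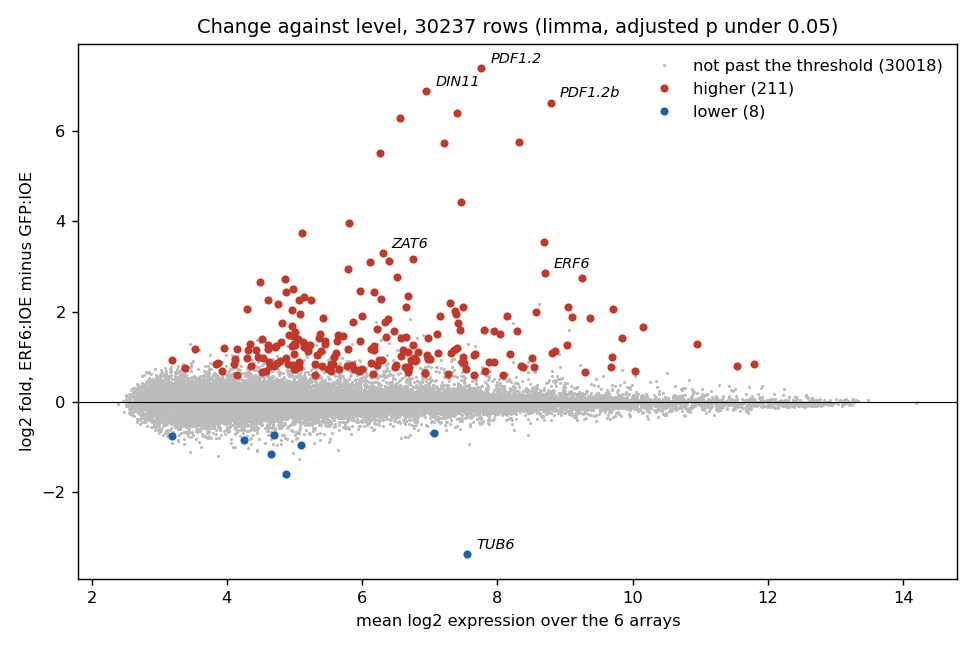
Log2 fold of ERF6:IOE over GFP:IOE (vertical axis) against the mean log2 expression over the 6 arrays (horizontal axis), 1 point per row, with the 211 rows higher in red, the 8 lower in blue and all others in grey. The red points reach 7.39 (PDF1.2), and the blue points lie at -1.59 or above except for TUB6 at -3.38.

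Transcripts of 3 defensins, small antimicrobial peptides, rose by log2 folds of 7.39 (PDF1.2, SE 0.60, 167-fold), 6.62 (PDF1.2b, SE 0.30, 98.5-fold) and 6.30 (PDF1.1, named LCR67 in the name table, SE 0.21, 78.5-fold). DIN11, a dark-inducible dioxygenase gene, rose from 3.51 ± 0.40 to 10.4 ± 0.09, a 118-fold difference with an adjusted p of 1.26e-05 (limma). The legume-lectin family genes AT3G15356 and AT3G16530 rose 84.4-fold and 54.0-fold, and the lectin gene AT1G78850 rose 11.6-fold. AT3G23550, of the MATE efflux family, rose 53.3-fold (SE of the log2 fold 0.11, limma adjusted p 2.51e-06). AT1G27020 rose 45.7-fold, the methyltransferase gene AT1G15125 21.7-fold and the acyltransferase gene AACT1 15.5-fold. The cytochrome P450 gene CYP71B22 rose 8.73-fold and AT4G18205 8.57-fold. Among these, PDF1.2 had the widest spread in GFP:IOE (SD 1.31), and its call held in 17 of 18 alternatives and was lost without repeat 3 of both lines (log2 fold 7.28, limma adjusted p 0.0633). Its GFP:IOE values ran from 2.70 to 5.31 and its log2 fold was 8.01 without GFP:IOE replicate 1 and 6.70 without replicate 2, so its fold and first rank are approximate. Mean levels in GFP:IOE of DIN11, PDF1.1, AT1G27020 and AACT1 lay below the lower quartile of each array (4.03 to 4.08). So did those of RAP2.9, GA2OX6, MYB51, WRKY28 and CYP81F2, named further on. On GFP:IOE replicate 3 alone, GA2OX6 (4.22) and CYP81F2 (4.17) lay above it. Values in that range are compressed and detection was not assessed, so the folds and order of these genes are approximate. The defensin genes are close in sequence, and signal shared between them was not separated.

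The transcription factor gene RAP2.9, of the AP2/ERF family, rose 13.3-fold (log2 fold 3.74, SE 0.12). The zinc finger gene ZAT6 rose from 4.65 ± 0.24 to 7.95 ± 0.44, or 9.80-fold, with an adjusted p of 0.00107 (limma). WRKY18, a regulator of defence genes, rose 9.02-fold (log2 fold 3.17, SE 0.15).

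**Figure D2:**
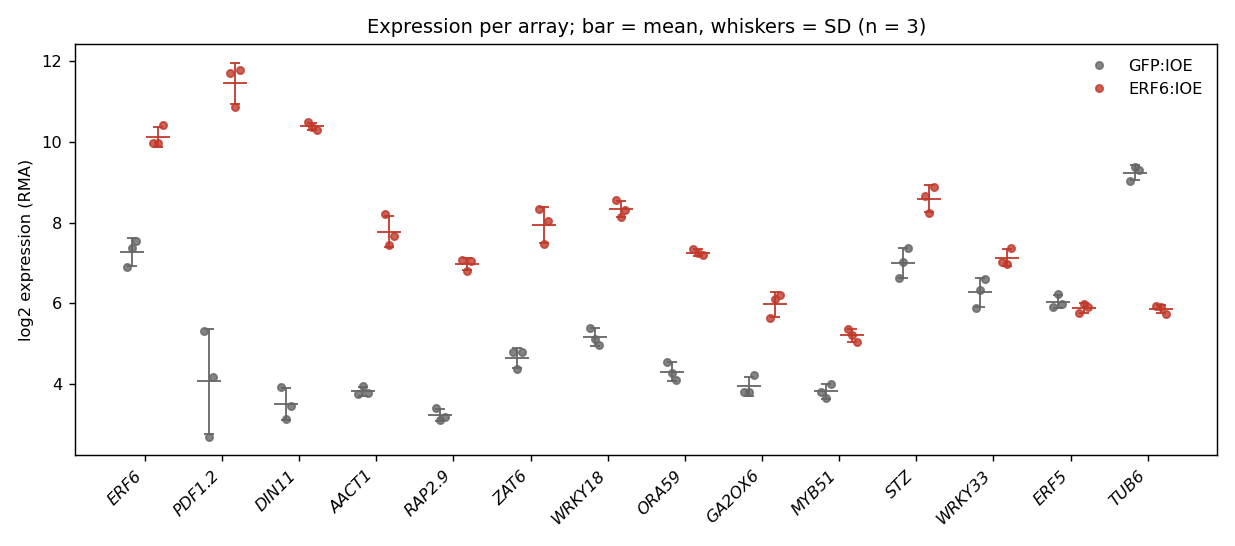
Log2 expression (vertical axis) of 14 named genes on each of the 3 arrays of GFP:IOE (grey) and of ERF6:IOE (red), with bars for the mean and whiskers for the SD. ERF6 lay at 7.27 and 10.1 on average and TUB6 at 9.24 and 5.87, while ERF5 lay at 6.04 and 5.89.

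The list of growth network transcription factors, ERF, WRKY, zinc finger and MYB factors linked to ERF6 in leaf growth, rose as a group. Of its 20 members 6 were higher, none was lower and 14 did not pass the test. ORA59, an ERF that acts in jasmonate and ethylene responses, rose by 2.95 (SE 0.13), ZAT6 by 3.29 (SE 0.23), STZ by 1.59 (SE 0.23) and MYB51, a regulator of indole glucosinolate synthesis, by 1.39 (SE 0.14). WRKY28 rose by 1.15 (SE 0.13) and WRKY15 by 1.05 (SE 0.13). WRKY33 had a log2 fold of 0.86 (SE 0.20) with an adjusted p of 0.19 (limma), and ERF11 of 0.59 (SE 0.17) with 0.321, so neither passed. The list's median log2 fold was 0.60 (limma camera, adjusted p 6.18e-12), and the adjusted p was 0.0357 with an estimated correlation. Adjusted over the list alone, 12 members were higher and 1, WRKY30 (-0.60), was lower. Several members are known as ERF6-linked from work on such lines, possibly including these arrays, so the list is not independent evidence of its direction. The call of MYB51 was lost without repeat 1 or repeat 2 of both lines (limma adjusted p 0.127 and 0.137), while the calls of STZ and WRKY28 held in 11 of 18 and 10 of 17 alternatives and were lost without any 1 of the 3 repeats (limma adjusted p up to 0.268 and 0.211). The call of WRKY28 was also lost with the repeat number as a block (limma adjusted p 0.051).

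Among genes that inactivate gibberellin, GA2OX6 rose from 3.95 ± 0.24 to 5.98 ± 0.31. This was 4.08-fold (log2 fold 2.03, SE 0.19, limma adjusted p 0.00413), and the call held in 17 of 18 alternatives, all but the one without repeat 2 of both lines (1.90, limma adjusted p 0.133). The other 6 measured members of the list did not pass, and the list was not called (median -0.13, camera adjusted p 0.904). GA2OX6 was also the 1 member called when adjusted over the list alone. None of 19 genes of gibberellin synthesis and signalling passed (median -0.05, camera adjusted p 0.677), with RGL1, a DELLA repressor gene, at -0.38 (SE 0.12).

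The list of defence and immunity genes was called higher, through a few members with large rises. Of 25 measured members 6 were higher and 19 did not pass. Besides the 3 defensins, PR4 rose 4.82-fold, PEN3, an ABC transporter gene of penetration resistance, rose 2.65-fold and the NADPH oxidase gene RBOHD 1.81-fold. The salicylic acid marker PR1 had a log2 fold of 0.01 (SE 0.20), while PR5 (0.93) and PEN2 (0.91) did not pass. The median was 0.05 and the mean 1.05 (limma camera, adjusted p 3.33e-06), and the median moved from 0.02 to 0.08 with 1 array left out and to 0.10 and 0.88 with the level filters. The filters rank rows by their mean over both lines, so a member dim in GFP:IOE stays in more easily if it rose. The filtered medians are therefore no measure of stability. The call was lost with an adjusted p of 0.206 with an estimated correlation. Adjusted over the list alone, 8 members were higher. The call of PEN3 held in 15 of 18 alternatives and was lost without repeat 1, 2 or 3 of both lines (limma adjusted p up to 0.127).

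Other lists held single genes that rose while the list was not called. In the jasmonate list, AOC1, an allene oxide cyclase gene of jasmonate synthesis, rose by 1.94 (SE 0.11) and the repressor gene JAZ6 by 0.85 (SE 0.10), and 23 of 25 members did not pass (camera adjusted p 0.677). CYP81F2, a P450 gene of indole glucosinolate modification, rose by 2.27 (SE 0.13), against 8 of 9 members of its list that did not pass (0.938). ERF15 rose 4.28-fold (SE of the log2 fold 0.11) among 18 other ERF and DREB factors (0.338), with ERF4 at 1.06 (SE 0.20, limma adjusted p 0.0885). WRKY18 was the 1 gene called among 16 other WRKY factors (0.216). XTH15 rose by 1.03 (SE 0.12) among 24 expansins and xyloglucan endotransglucosylases (0.904). Adjusted over the list alone, the counts were 3 higher and 1 lower for jasmonate and for other ERF and DREB factors, 1 higher and 1 lower for indole glucosinolates, and 1 higher for other WRKY factors and for XTH genes and expansins. The calls of JAZ6 and XTH15 held in 9 and 11 of 18 alternatives and were lost without any 1 of the 3 repeats (limma adjusted p up to 0.25 and 0.163). Both were also lost with the repeat number as a block (limma adjusted p 0.0595 and 0.0566).

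**Figure D3:**
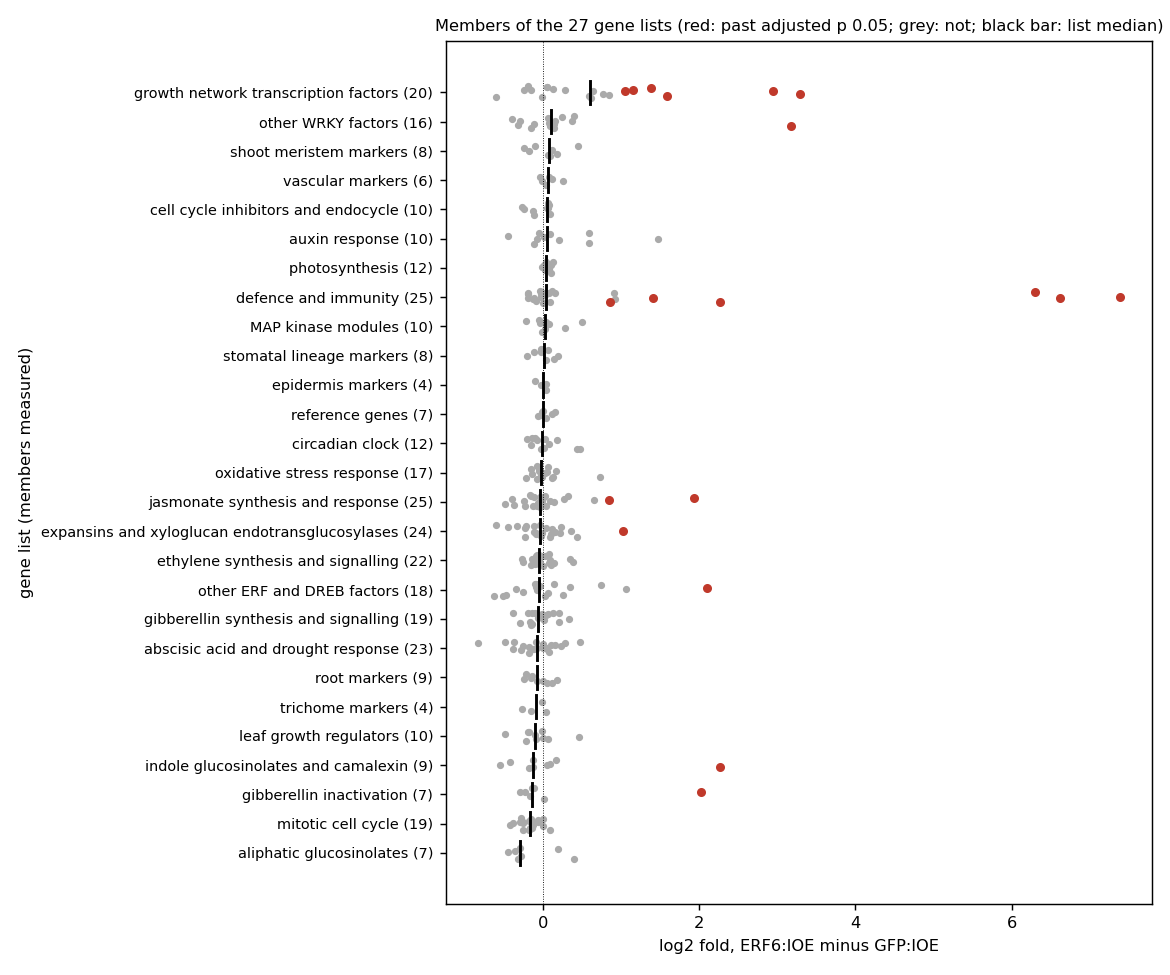
Log2 fold of ERF6:IOE over GFP:IOE (horizontal axis) of every measured member of the 27 gene lists (vertical axis, with the number measured). The growth network list has a median of 0.60 and the mitotic list of -0.16, while the medians of the root, trichome and other marker lists lie between -0.08 and 0.08.

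Mitotic cell cycle genes were slightly lower as a group, with no single member past the test. Of 19 members, 16 had a negative log2 fold, and the median was -0.16 (limma camera, adjusted p 6.76e-05). The adjusted p was 0.206 with an estimated correlation, so the call was lost there. CDT1A, a replication licensing gene, had a log2 fold of -0.42 (limma adjusted p 0.24), the D-type cyclin gene CYCD3;3 of -0.38 (SE 0.13) and the B-type cyclin gene CYCB1;1 of -0.26 (SE 0.10). No member passed when adjusted over the list alone. Cell cycle inhibitors and endocycle genes were not called (median 0.06, camera adjusted p 0.844), nor were leaf growth regulators (median -0.10, 0.644). Among the latter, ANT, a growth-promoting factor gene, had a log2 fold of -0.48 (SE 0.10, limma adjusted p 0.119). Adjusted over the list alone, GRF3 was higher (0.46) and ANT lower.

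No member passed in the other lists of hormone and stress genes. Medians were -0.04 for 22 ethylene genes (camera adjusted p 0.904), 0.03 for 10 MAP kinase module genes (0.644), -0.07 for 23 abscisic acid and drought genes (0.56), -0.02 for 17 oxidative stress genes (0.838) and -0.29 for 7 aliphatic glucosinolate genes (0.427). Among 10 auxin response genes the median was 0.06 (0.193), with IAA2 at 1.47 (SE 0.25) and an adjusted p of 0.0614 in limma. Adjusted over the list alone, 3 auxin genes were higher and 1 lower. EIL1 (0.39), MPK3 (0.50), ABI1 (-0.37), CYP707A3 (-0.83) and GSTF6 (0.73) did not pass.

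Lists that mark tissues or general function were not called either, and none of their members passed. Medians were 0.05 for photosynthesis (camera adjusted p 0.503), -0.01 for the circadian clock (0.689), -0.08 for root (0.644), 0.08 for shoot meristem (0.904), 0.01 for the stomatal lineage (0.69), -0.08 for trichomes (0.644), 0.06 for vascular tissue (0.644) and 0.01 for the epidermis (0.904). The 7 reference genes had a median of 0.01 (0.703). Median, mean and tests differed in sign for 10 of the 27 lists, none of them called. Those were other ERF and DREB factors, gibberellin inactivation, ethylene, jasmonate, oxidative stress, indole glucosinolates, cell cycle inhibitors, expansins, the circadian clock and the epidermis.

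The strongest fall was in TUB6 (AT5G12250), a beta-tubulin gene, from 9.24 ± 0.18 to 5.87 ± 0.10. It was 10.4-fold lower (log2 fold -3.38, SE 0.12, limma adjusted p 3.63e-05), and the call held in 18 of 18 alternatives. The other 7 genes that fell changed less. AT3G24005, a transcribed pseudogene in the name table, was 3.00-fold lower, AT1G61180 2.21-fold and AT2G04910 1.93-fold. COW1, a root hair gene, was 1.78-fold lower, AT1G33925 1.67-fold and AT1G49850 1.62-fold. COW1 in ERF6:IOE and AT2G14692, which also fell, in both lines lay below the lower quartile of each array, so the size of these falls is approximate. Their limma adjusted p-values lay between 0.0172 and 0.047, and each of these 7 calls was lost in some alternatives, held by 4 of 17 for AT1G33925 up to 10 of 17 for AT1G61180. With the repeat number as a block, all of the 7 but AT1G61180 lost their call (limma adjusted p 0.051 to 0.115). Arrays without induction were not analysed here, so differences between the lines before induction were not separated from those after it.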

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

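Averaging the rows of a locus and leaving out leading list members were chosen after the data were seen. ERF6 was higher in all 17 alternatives that tested it, with a log2 fold from 2.66 to 2.99 when a repeat or an array was left out and adjusted p-values from 0.000154 to 0.0354 (limma). No called result changed direction. For genes this was largely fixed in advance, since the lines did not overlap in any called row and several alternatives leave the log2 fold unchanged. Of all 2326 named gene values under alternatives 29 changed sign, and of all 540 list directions 47, each of a gene or list that did not pass.

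The labels do not say that a repeat number marks a shared experiment. Same-numbered arrays of the lines had correlations of deviations of 0.19, 0.078 and 0.21 over all rows, and of 0.44, 0.17 and 0.44 over the brighter 50% of rows. The main fit treated them as sharing only a number. Each array nevertheless correlated best with its own number, which points to a pairing, so calls that the block ends are uncertain. With the number as a block, 143 rows were higher and 5 lower, and 128 of the 148 were among the 219. Called lists stayed at 2 higher and 1 lower. Of the named genes, 9 lost their call, namely WRKY28, JAZ6, XTH15 and 6 of the 8 lower genes (all but TUB6 and AT1G61180), and IAA2 passed (adjusted p 0.02). Over all alternatives IAA2 passed in 7 (0.02 to 0.433), ERF4 in 3, AOC2 in 2 and IAA29 and ANT in 1 each.

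Rows higher were 277 above the 30th percentile of level, 268 above the median, 198 after renewed quantile normalization, 210 after centring, 220 after cyclic loess, 277 with a variance trend, 226 with array weights, 211 with a minimum fold and 212 with averaged rows. Rows lower were 14 and 22 with the filters, which test fewer rows, and 6 to 11 otherwise. Without GFP:IOE replicate 1, 2 or 3, 107, 89 and 126 rows were higher and 2, 6 and 6 lower. Without ERF6:IOE replicate 1, 2 or 3, 126, 87 and 97 were higher and 3, 1 and 2 lower. With a repeat left out of both lines, 45 to 53 were higher and 1 to 2 lower, with fewer samples.

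With an estimated correlation 1 list was higher and 0 lower. With fry 3 were higher, adding the reference genes (adjusted p 0.0309), and 1 lower. At the preset correlation, the defence list passed without its 3 defensins (adjusted p 0.0367) and the growth network list without its 2 largest members (1.45e-07), but the full defence list already missed the threshold with an estimated correlation (adjusted p 0.206). Leaving out arrays gave 2 to 4 lists higher and 1 to 2 lower. Without GFP:IOE replicate 3 other ERF and DREB and other WRKY factors were called higher (0.0299 each), without ERF6:IOE replicate 3 the abscisic acid list lower (0.0247), and without ERF6:IOE replicate 1 the auxin list higher (0.0191, and 0.0372 without replicate 1). Signal over background was not analysed here.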

Other observations

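Genes in this paragraph were chosen after their values were seen. Besides the listed genes, methyltransferase genes of indole glucosinolate metabolism rose. Their log2 folds were 2.74 for IGMT4, 2.65 for IGMT1 and 2.06 for IGMT2. These genes follow one another in the locus order of the array's rows and are close in sequence. Mean levels in GFP:IOE of IGMT1, IGMT2, PRXCA and GSTU12 lay below the lower quartile of each array, so their folds are approximate. Glutathione transferase genes GSTU13 (2.11), GSTF10 (2.06) and GSTU12 (1.17) rose, as did the peroxidase gene PRXCA (2.72) and the aquaporin genes PIP1A (1.67) and PIP2A (0.83). By symbol prefix, only 2 of 27 GSTU, 1 of 13 GSTF and 2 of 20 PIP genes were called higher. SIB2 (1.87) and MKS1 (0.77), which encode proteins that bind WRKY factors, also rose, as did NIA2 (1.05) and NRT1.7 (1.23), genes of nitrate reduction and transport. Among 20 genes of the ROT4-like family of small growth-restricting peptides, ROT4 rose 5.04-fold (log2 fold 2.33, SE 0.13) and RTFL8 1.59-fold. RTFL18 was also called higher but lay below the lower quartile in both lines, where detection was not assessed, and none was called lower, while RTFL12 (1.59, SE 0.40) did not pass. Families defined by symbol prefix were also tested for an excess of genes that rose, and 0 of 478 passed Benjamini-Hochberg adjustment with Fisher's exact test, one-sided, against 7 at an unadjusted p under 0.05. Prefixes split related genes, with PDF1.1 counted under LCR and ROT4 apart from RTFL. The result therefore does not show that no gene family rose. Neighbours were loci next to each other in the locus order of the array's rows. Those that both rose formed 9 pairs, against a median of 1 in 10000 shuffles, of which 1 gave as many. Related neighbours can share signal.

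Tests chosen only after the result was seen were those of the array centre and of falls near the floor and all 3 on TUB6. The number of genes called was as large in 1 of the 10 splits of the 6 arrays, the real one, with 219 genes against at most 0 in another split. For lists, 5 of 10 splits gave as many as the real 3, and the highest other gave 12. These splits are too few for a share under 0.05. Splits that kept both repeat 1 arrays together called 12, 7, 6 and 2 lists and the other 5 besides the real one called 3, 0, 0, 0 and 0, with 0 in each of the 3 that took 1 array of every number, which points to a structure by repeat number, and the blocked fit called 2 lists higher and 1 lower. In other splits the mitotic list had adjusted p-values of 0.0711 or above and the growth network list of 0.0661 or above, whereas the defence list passed in 2 (0.0279 and 0.045, limma camera). The size of the defence list's median log2 fold was 0.0454 in the real split and from 0.0141 to 0.155 in the others. Its median therefore does not set the real split apart.

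Of the genes called, 211 were higher and 8 lower. Values centred too high in ERF6:IOE would need an offset of 0.26 to balance the calls, and the reference genes had a median of 0.00501 (bootstrap interval -0.02 to 0.11), which argues against it, although fry called them higher (mean 0.03, adjusted p 0.0309), a smaller offset than 0.26. Falls hidden near the floor are argued against by the 25% of rows brightest in GFP:IOE, where 2 of 58 calls (3.45%, exact 95% interval 0.42 to 11.9%) were lower. A biological difference between the lines stays open and was not tested.

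TUB6 fell by 3.38 on the log2 scale. A general fall of tubulin transcripts is argued against by the other 11 tubulin genes, with a median of -0.0299 (from -0.19 to 0.37, 0 called). A change spanning neighbouring genes is argued against by the 6 nearest rows, the lowest at -0.47 (lower 95% bound -1.27, against -3.67 to -3.09 for TUB6, 0 called). Turnover after induction would need a half-life of at most 1.18 h even if synthesis stopped at once, and no half-life was measured, so it remains open. A difference of the line that predates induction, such as an insertion in the gene, may also account for it and was not tested.

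The mitotic list had a median of -0.16. A trend with level is argued against by level-matched lists, of which 0% of 10000 had a median as low (95% of them from -0.08 to 0.06). A single deviating array is argued against by medians from -0.21 to -0.136 with 1 array left out. Correlation among its members remains open, since the adjusted p was 0.206 with an estimated correlation. A biological difference between the lines also stays open and was not tested.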
